A study of Mus musculus with 15 samples.

How the data were processed

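The data are 3′ RNA-seq counts from mouse brain in 15 libraries, 5 each of wild types given saline, Tbx1 heterozygotes given saline and Tbx1 heterozygotes given vitamin B12. Groups and replicate numbers were taken from the sample titles. The labels call the tissue both whole brain and brain hemisphere, and they name more than 1 way of isolating RNA (Qiazol with an added precipitation, and RNeasy Plus kits) without saying which library had which. The labels carry an animal number per library; 1 number stands on both Het_PBS 5 and Het_B12 1, whose counts differed by a chi-square of 11.36 per degree of freedom. The lowest such value among the 30 pairs within groups was 3.14, so no library was treated as a duplicate. Against the other Het_B12 libraries Het_PBS 5 stood at 9.73 to 11.63. The value for the pair therefore cannot tell whether both came from 1 mouse. Nothing in the labels states outright that each library came from a separate mouse, and p-values measure the spread between these libraries. No batch or date is given in the sources used here.

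The authors deposited 1 table of raw read counts per gene and library. Per the submitters' processing notes the tools were STAR, HTSeq and edgeR and the genome build was mm10; versions, annotation, strand setting, removal of duplicate reads and any filter are not given in the sources used here. Libraries were made with the QuantSeq 3′ protocol, per the labels' protocols. The deposited counts are whole numbers for 30386 gene identifiers, 9918 of them at 0 in every library, and no column was left unmapped. Of these identifiers 30348 (99.87%) matched the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, which gave coordinates and transcript lengths. Symbols were those deposited with the counts, where 71 identifiers share a symbol with another. Totals of 1683258 to 2746122 counts make 3 counts equal to 1.78 to 1.09 CPM. Intervals and floors cover counting error only. A 3′ count does not depend on transcript length in principle, reads that map to several near-identical genes can be lost or split, and internal priming at A-rich stretches can give reads outside 3′ ends. Globin, ribosomal protein and metallothionein genes have near-identical relatives, and their single counts are uncertain for that reason. Of 91 genes named in the text, 40 overlap another annotated gene, 30 of them on the opposite strand. For 9 of the 40 (Dgcr8, Chrd, Rgs11, Pcdhgc5, Ankrd52, Cx3cr1, Pi4ka, Dcp1a and Slc39a2) an overlapping gene had more than 10% as many reads. For Pcdhgc5 and Slc39a2 such genes lie on the same strand, so these values are uncertain under any strand setting. For the others they lie on the opposite strand, so those values are uncertain without a stated strand setting.

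Counts were analysed in R 4.3.3. Genes were kept by filterByExpr, which left 11718, and scaled by TMM factors in edgeR 4.0.16. A quasi-likelihood model was fitted to all 15 libraries with 1 mean per group and no covariates, 12 residual degrees of freedom and a biological coefficient of variation of 0.181, and contrasts were tested with glmQLFTest. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 with standard errors; CPM are TMM-normalised. The test of any difference among the 3 groups was an F test in the same fit. On simulated counts with 100 genes changed 2-fold and 100 changed 1.5-fold, the contrast test recovered 71% and 33% for Het_PBS against WT_PBS. Recovery was 66% and 29% for Het_B12 against Het_PBS and 66% and 23% for Het_B12 against WT_PBS. False calls were 8.77%, 5% and 4.3% of calls. The F test was not tried in this way.

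The 48 gene lists of cell types, brain regions and pathways were written from textbook knowledge. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, two-sided and adjusted over the 48 lists of a comparison, and again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance and compares it with no other genes. The 15, 10 and 10 lists called are described in the report. The tests, lists and the rule for named genes were fixed before the data were examined. The rule took Tbx1; the 10 largest rises and falls among genes that passed with a mean of at least 1 CPM, or, where fewer passed, the smallest p-values up to 5 per direction, given as values that did not pass; up to 4 members with the smallest p of each list described; and passing members of the Tbx1 neighbourhood, vitamin B12 and sex-linked lists. Predicted genes could be summarised. Some genes that the rule selects are not reported here and are left out of the counts of named genes.

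Alternatives set in advance were DESeq2 size factors, no filter on low counts, a mean count of at least 50, DESeq2 1.42.0 (Wald tests, and a likelihood ratio test over the 3 groups), limma-voom with and without quality weights, a fit of only the 2 groups compared, the replicate number as a block, 1 surrogate variable from sva 3.50.0 and leaving out each library in turn. Added after seeing the data were fits without Gm42418 and mitochondrial genes, without WT_PBS 3 and Het_PBS 5 together, without Het_PBS 1 and Het_PBS 3 together, and with an offset for transcript length, made from a loess curve of each library's deviation on the log2 length of the longest transcript (known for 99.95% of tested genes). A sex covariate was not run, since Y-linked genes had reads in all 15 libraries. For comparisons that share libraries, counts with no effect were simulated 20 times and the shared libraries were divided into disjoint sets of 2 and 3. Group labels were set in 100 splits per comparison, the real one included. For a test of depth, each library was thinned at random to 1683258 counts. Correlations over the 10 PBS libraries used values centred by group and 1e+05 permutations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.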

Results

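Gene expression was measured in the brains of adult mice by QuantSeq, a method that reads the 3′ ends of polyadenylated RNA, so that a count reflects transcript number rather than transcript length. The mice were wild type or carried 1 mutant copy of Tbx1, a T-box transcription factor gene in the chromosomal region that corresponds to the human 22q11.2 deletion. The 15 libraries fall into 3 groups of 5: wild types given phosphate-buffered saline (WT_PBS), heterozygotes given saline (Het_PBS) and heterozygotes given vitamin B12 at 20 mg/kg (Het_B12). Injections were intraperitoneal, 2 per week for 4 weeks from 4 weeks of age. Wild types given the vitamin were not analysed here. Total counts ran from 1683258 (Het_PBS 5) to 2746122 (Het_B12 5), with group means of 2225700 ± 407310 in WT_PBS, 2293300 ± 383600 in Het_PBS and 2517000 ± 272880 in Het_B12 (SD, n = 5). A count of 3 reads, used as the detection floor, corresponded to 1.09 to 1.78 CPM (counts scaled to library size) across libraries. Of the 30386 genes in the table, 11718 had enough reads to be tested.

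Tbx1 itself (ENSMUSG00000009097, GRCm38 chromosome 16, 18580979 to 18590671, minus strand) was close to undetected in these brains. It had 3 reads in WT_PBS, all in WT_PBS 4, 3 in Het_PBS, all in Het_PBS 1, and 1 in Het_B12, in Het_B12 4. These counts are at or under the floor, so no fold is given and the genotype labels were not checked by them. Which part of Tbx1 the mutant allele lacks is not given in the sources used here. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y had reads in all 15 libraries.

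The largest axis of variation followed the vitamin group. The first principal component held 18.1% of the variance and placed the 5 Het_B12 libraries at 19.1 to 32.8. WT_PBS 3 lay near them at 17.8, while the other 9 PBS libraries lay between -22.4 and -10.2. Het_PBS 5 lay farthest out on the second component, at -43.5. Gm42418, a locus that collects ribosomal RNA reads, took 11.9% ± 1.78 of the counts in WT_PBS, 8.52% ± 1.73 in Het_PBS and 5.29% ± 1.25 in Het_B12. Mitochondrially encoded genes took 7.29% ± 1.32, 9.75% ± 1.33 and 8.47% ± 0.688, in the same order (SD, n = 5 per group).

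**Figure D1:**
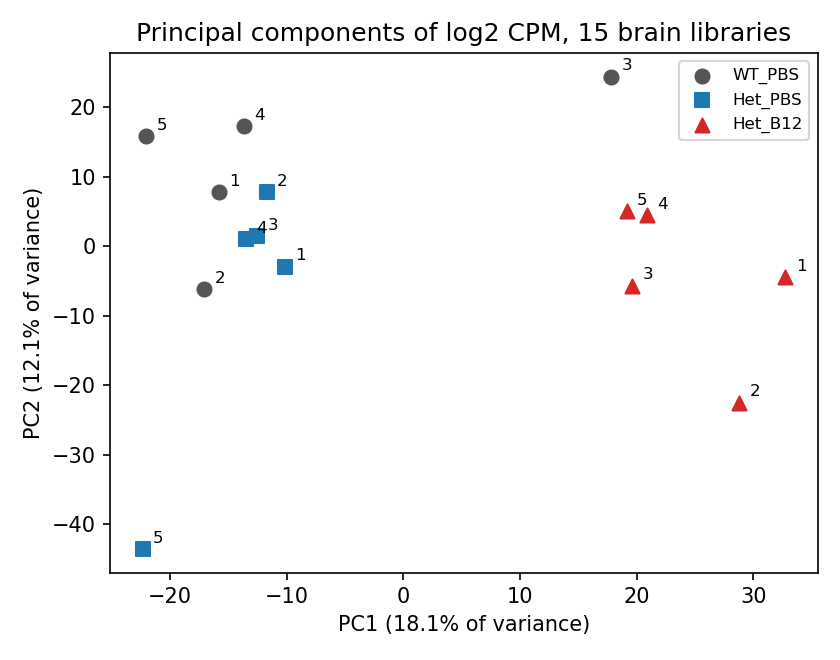
Each point is 1 brain library on the first 2 principal components of log2 CPM (axes in component units, with the percentage of variance), with the replicate number beside it and shape and colour for the group. The 5 Het_B12 libraries lie at 19.1 to 32.8 on the first component, with WT_PBS 3 at 17.8.

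Heterozygous brains were first compared with wild-type brains under saline, which asks what the loss of 1 Tbx1 copy does. No gene passed the test. The genes with the smallest p-values on the higher side in Het_PBS were Hbb-bt (log2 fold change 1.55 ± 0.31 SE) and Hbb-bs (1.30 ± 0.27), which encode β-globins, each with an adjusted p of 0.125. Hbb-bt stood at 237 ± 204 CPM in Het_PBS and 80.9 ± 30.9 CPM in WT_PBS (SD, n = 5), a spread wider than the difference, and without Het_PBS 3 the log2 fold change of Hbb-bt was 0.91. Spag7 (0.70 ± 0.16), the ribosomal protein gene Rps3a1 (0.83 ± 0.19) and the α-globin gene Hba-a2 (1.29 ± 0.30) followed, each with an adjusted p of 0.226. Without Het_PBS 3 Hba-a2 was at 0.70. On the lower side were Cbln3, a cerebellar granule cell gene (-0.64 ± 0.15, adjusted p = 0.226), the predicted gene 4932438A13Rik (-0.45 ± 0.11, 0.378), Mroh2a (-1.11 ± 0.29, 0.387), the splicing factor gene Sfswap (-0.60 ± 0.16, 0.442) and Tor1b (-0.56 ± 0.15, 0.444). None of these values passed.

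As groups, 10 of the 48 gene lists fixed before the data were examined differed between Het_PBS and WT_PBS by camera with its preset correlation, 9 of them higher in Het_PBS. Differences followed transcript length, with a median log2 fold change of 0.0407 in the fifth of genes with the shortest transcripts and -0.0575 in the longest (Spearman's rho -0.145 across genes, which are not independent replicates). With an offset for transcript length the hypothalamic (0.111) and hypoxia (0.0582) lists did not pass. No member of any of the 10 passed over all genes. Of 76 tested cytosolic ribosomal protein genes, 66 lay above 0, and 3 were higher when adjusted over the list alone, Rps3a1 and Rps23 (0.80 ± 0.22) having the smallest p-values (camera adjusted p = 2.49e-15; adjusted p = 0.444 with an estimated correlation). All 10 erythroid genes lay above 0, 4 of them past the threshold adjusted over the list alone, with Hbb-bt and Hbb-bs leading (camera adjusted p = 1.44e-07; adjusted p = 0.365 with an estimated correlation). Haemoglobin genes took 0.216% ± 0.167 of the counts in Het_PBS against 0.0844% ± 0.0319 in WT_PBS, and without Het_PBS 1 and Het_PBS 3 together the erythroid p was 0.166. The 72 nuclear genes of the respiratory chain, such as Cox6b1 (0.43 ± 0.13) and Cox8a (0.50 ± 0.15), had 54 members above 0 and 0 past the threshold adjusted over the list alone (camera adjusted p = 1.46e-06; adjusted p = 0.51 with an estimated correlation; 0.217 without WT_PBS 3 and Het_PBS 5 together). Among 10 mitochondrially encoded genes, 5 were higher adjusted over the list alone, among them mt-Nd4 (0.49 ± 0.13) and mt-Cytb (0.43 ± 0.13), at a camera adjusted p of 4.76e-06 (adjusted p = 0.376 with an estimated correlation).

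The 6 remaining lists had larger p-values. The 34 glutathione and antioxidant genes, with Mt2 at 0.58 ± 0.15, had 1 member higher adjusted over the list alone (camera adjusted p = 0.00416). The 27 unfolded protein and heat shock genes, with Cryab at 0.41 ± 0.16, had 0 (0.00375), the 14 glucocorticoid-responsive genes had 1 (0.00983), the 16 hypothalamic and neuropeptide genes had 0 (0.0282) and the 16 hypoxia genes, with Egln1 at 0.50 ± 0.15, had 1 (0.0401). The 21 cerebellar neuron markers were the list that lay lower, with 16 members below 0, 1 member lower adjusted over the list alone, Gabra6 at -0.51 ± 0.21 and Neurod1 at -0.38 ± 0.16 (camera adjusted p = 0.00588). With an estimated correlation the adjusted p of these 6 lists lay between 0.365 and 0.51. Without WT_PBS 3 the cerebellar (0.102), glutathione (0.137) and unfolded protein (0.0714) lists no longer passed. The glucocorticoid list was lost without Het_PBS 3 or Het_PBS 5, the hypothalamic list without Het_PBS 3, WT_PBS 1, WT_PBS 2 or WT_PBS 3, and the hypoxia list without any single WT_PBS library, Het_PBS 3 or Het_PBS 5, with adjusted p up to 0.16, 0.445 and 0.16.

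Of the genes tied to the design, none passed over all genes by genotype. Of 28 tested genes in the Tbx1 neighbourhood, which lie close to Tbx1 on chromosome 16, none passed, including adjusted over the list alone. Dgcr8, a microRNA processing gene, stood at -0.55 ± 0.22 and Lztr1 at 0.30 ± 0.15 (camera adjusted p = 0.424). Of 18 genes of vitamin B12 uptake and use, 0 passed and 1 was higher adjusted over the list alone. Thap11 was at 0.84 ± 0.23 and Tcn2, which encodes the blood carrier transcobalamin, at -0.66 ± 0.31 (camera adjusted p = 0.323). The folate and methionine cycle (25 genes, 0.502), glutamate and glutamine metabolism (25 genes, 0.115; Glul, glutamine synthetase, at 0.40 ± 0.12) and γ-aminobutyric acid (GABA) signalling (24 genes, 0.897) had 0 members past either threshold.

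The count of 0 genes came from edgeR's quasi-likelihood test, in which 879 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.125. DESeq2 and limma-voom also called 0, and 98 genes (0.836%) had no overlap between the groups, against 0.794% by chance. On simulated counts of this design the test recovered 71% of 2-fold and 33% of 1.5-fold changes. The count was 14 without WT_PBS 2, 5 without Het_PBS 2, 2 without Het_PBS 4 and 2 without Het_PBS 5, 40 without a filter on low counts and 5 with 1 surrogate variable, and 2 with every library thinned to the smallest total. Of the 25 named genes, 9 passed in at least 1 fit without a library, Hbb-bt and Hbb-bs in 4 fits each.

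Vitamin B12 was examined in heterozygotes by comparing Het_B12 with Het_PBS, and 851 genes changed, 407 of them higher and 444 lower. Flt1, which encodes a receptor for vascular endothelial growth factor (chromosome 5, 147561604 to 147726011), rose 2.89-fold, from 25.1 ± 8.6 to 71.5 ± 15.8 CPM (SD, n = 5; log2 fold change 1.53 ± 0.19 SE, edgeR adjusted p = 3.79e-06). S100b, an astrocyte calcium-binding protein gene (chromosome 10, 76253853 to 76261159), fell from 1357 ± 173 to 770 ± 51.6 CPM (-0.82 ± 0.10, 3.87e-06). C1qa, a complement gene of microglia (chromosome 4, 136895917 to 136898803), fell from 89.2 ± 13.8 to 44.5 ± 4.52 CPM (-1.0 ± 0.15, 5.03e-05). For all 3 genes no Het_B12 library overlapped the Het_PBS range. Of the changed genes, 146 differed by more than 2-fold.

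By size of change, Sec14l5 (2.27 ± 0.51 SE), Gtpbp2, a GTP-binding protein gene (1.96 ± 0.37), Pecam1, an adhesion molecule of endothelium (1.93 ± 0.55), Chrd, the bone morphogenetic protein antagonist chordin (1.87 ± 0.50), and Tbc1d31 (1.84 ± 0.57) rose most. Rgs11, a regulator of G-protein signalling (1.80 ± 0.33), the transcription factor gene Mlxip (1.80 ± 0.47), the protocadherin gene Pcdhgc5 (1.79 ± 0.51), the long non-coding RNA Miat (1.77 ± 0.29, from 32.8 ± 7.86 to 113 ± 33.8 CPM) and Ankrd52 (1.71 ± 0.53) completed the 10 largest rises. All but Miat were at 16.9 CPM or less, Gtpbp2 being the highest, in Het_B12, with edgeR adjusted p from 0.000105 (Miat) to 0.0397 (Ankrd52). Chrd, Rgs11 and Ankrd52 overlap genes with reads on the opposite strand, so their counts are uncertain without a stated strand setting. Pcdhgc5 overlaps other protocadherin genes with reads on its own strand, so its count is uncertain under any strand setting. The call of Tbc1d31 was lost in 8 of the 15 fits without 1 library (highest adjusted p 0.109, without Het_PBS 4), of Pecam1 in 6 (0.0674, without Het_PBS 4), of Ankrd52 in 6 (0.136, without Het_B12 1), of Pcdhgc5 in 3 (0.109, without Het_B12 1) and of Mlxip in 1 (0.0518, without Het_PBS 4). Without Het_PBS 1 and Het_PBS 3 together Chrd did not pass (adjusted p = 0.145), and Pecam1 was at 3.44 and Ankrd52 at 2.38. With an offset for transcript length Ankrd52 did not pass (0.0608). By limma-voom Tbc1d31 (0.15) and Ankrd52 (0.128) did not pass, nor did Tbc1d31 by DESeq2 (0.0517).

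The falls were led by genes left nearly without reads in Het_B12. Mroh2a (chromosome 1, 88226986 to 88262289) fell from 23.1 ± 6.77 to 0.888 ± 1.80 CPM (log2 fold change -4.83 ± 0.48, edgeR adjusted p = 3.31e-08). Het_B12 1, at 4.09 CPM, carried most of that mean, and without it the log2 fold change of Gm26870 was -3.98 and of Gm10800 -3.46. In the other Het_B12 libraries Mroh2a and Slc2a9 were under the floor of 3 reads and Olfr432 and Pramel1 had 0 reads, so no fold is given for these 4 genes without Het_B12 1. Gm15839 was at -4.32 without Het_B12 5, on few reads, since its 10 reads in Het_B12 lay in 2 libraries. Slc2a9, a urate transporter gene, fell by 3.92 ± 0.75, the odorant receptor gene Olfr432 by 3.64 ± 0.83, and the predicted gene Gm15839 by 3.45 ± 0.57 on the log2 scale. Slc2a9 was at -3.32 without Het_PBS 2. The predicted genes Gm26870 and Gm10800 stood at -2.91 ± 0.51 and -2.85 ± 0.52. Pramel1 had 2 reads in Het_B12 against 39 in Het_PBS, 23.5-fold fewer relative to depth (95% interval of counting error 6.08 to 201). Olfr432 had 4 reads in Het_B12 against 51 (15.4-fold, 5.64 to 58.5), all 4 in Het_B12 1. In the same libraries, the summed level of 1447 olfactory, vomeronasal and trace amine receptor genes was 17.2 ± 5.6 CPM in Het_B12 (n = 5). It was 89.6 ± 25.5 CPM in the PBS libraries (n = 10, exact two-sided permutation p = 0.00033). Only 351 of these genes had reads, which numbered 225 in Het_B12 and 1937 in the PBS libraries. S100a8 and S100a9, the calprotectin subunits of neutrophils, fell by 3.63 ± 0.58 and 2.75 ± 0.54, and Tsacc by 2.15 ± 0.55 on the log2 scale, the call of Tsacc being lost without Het_PBS 4 (adjusted p = 0.0516). S100a8 was at -2.92 without Het_PBS 5 and S100a9 at -3.44 without Het_B12 2.

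**Figure D2:**
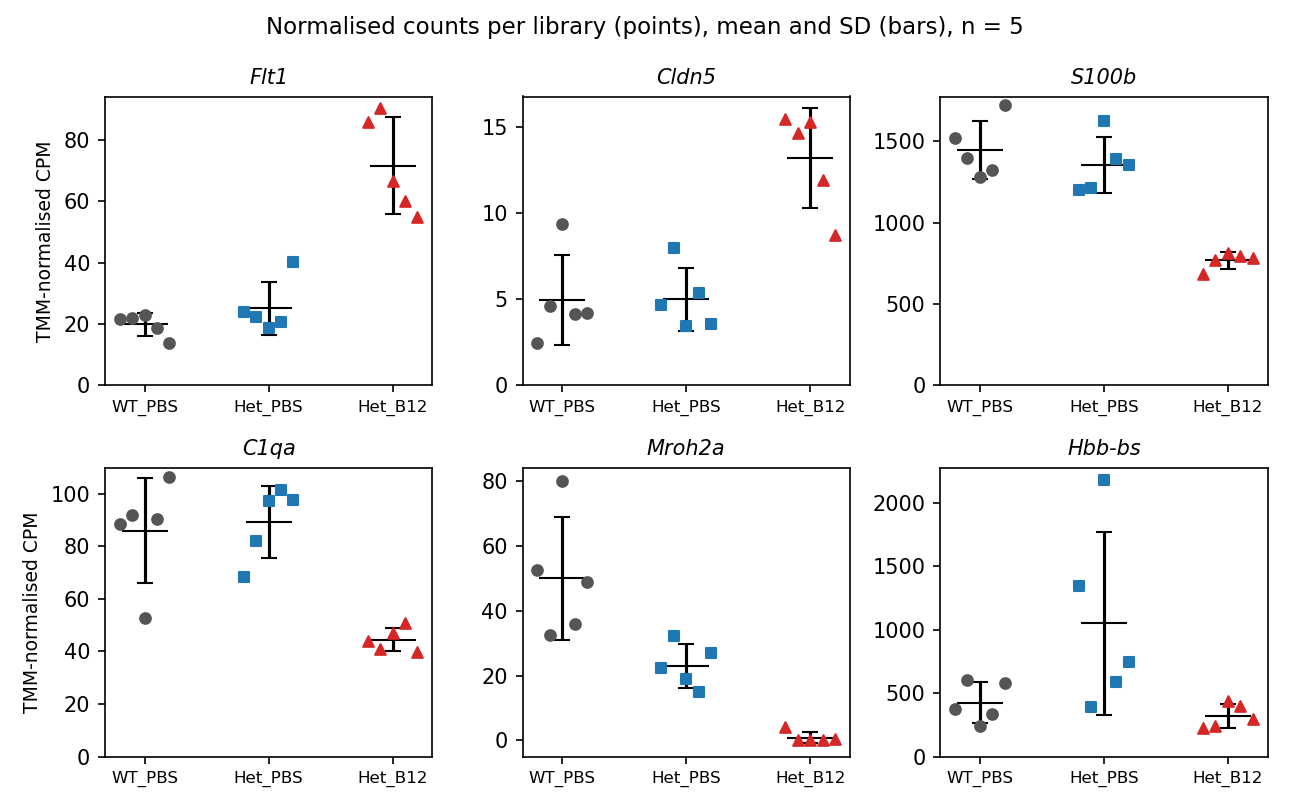
Normalised CPM of 6 genes (vertical axes) in the 3 groups (horizontal axes), with 1 point per library and bars for the mean and SD (n = 5). Flt1 and Cldn5 were higher and S100b, C1qa and Mroh2a lower in Het_B12, while Hbb-bs was widest in Het_PBS.

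Endothelial markers lay higher with the vitamin, and astrocyte and microglia markers lower. Other vessel and glial lists did not pass: oligodendrocyte and myelin markers (27 genes, 4 lower, camera adjusted p = 0.148), oligodendrocyte precursor markers (0.863), pericyte and smooth muscle markers (0.803) and genes of VEGF and Notch signalling in vessels (0.195). Of 21 endothelial markers, 6 rose, 0 fell and 15 did not pass; adjusted over the list alone, 12 rose and 1 fell. Examples were Flt1, Slco1a4, a transporter of the blood-brain barrier (1.38 ± 0.23), Pecam1 and the tight junction gene Cldn5 (1.37 ± 0.35; camera adjusted p = 1.1e-07; adjusted p = 0.0821 with an estimated correlation). Of 22 astrocyte markers, 12 fell and 10 did not pass, with 15 lower adjusted over the list alone, among them S100b, the gap junction gene Gjb6 (-0.80 ± 0.15) and Clu (-0.51 ± 0.10; camera adjusted p = 2.85e-13; adjusted p = 0.0821 with an estimated correlation). Of 21 microglia markers, 6 fell and 15 did not pass, with 12 lower adjusted over the list alone, including the protease gene Ctss (-1.12 ± 0.16), C1qa and the fractalkine receptor gene Cx3cr1 (-0.57 ± 0.12; camera adjusted p = 2.94e-09; adjusted p = 0.0821 with an estimated correlation). Cx3cr1 overlaps Wdr48, which makes its count uncertain without a stated strand setting. Of 17 meningeal and fibroblast markers, 5 fell and 9 did so adjusted over the list alone, for example Mgp (-1.15 ± 0.22) and Ptgds (-0.68 ± 0.14; camera adjusted p = 2.12e-06; adjusted p = 0.0821 with an estimated correlation). Of 7 leukocyte markers, 3 fell, and the same number fell adjusted over the list alone, with S100a8, S100a9 and the lysozyme gene Lyz2 (-1.18 ± 0.30) leading (camera adjusted p = 0.000208; adjusted p = 0.0821 with an estimated correlation). The call of Lyz2 was lost without Het_PBS 5 (adjusted p = 0.0551). The astrocyte level, a mean of log2 CPM relative to WT_PBS, was -0.336 ± 0.138 in Het_B12 and 0.0884 ± 0.0346 in Het_PBS; WT_PBS 3, given saline, stood at -0.311, and at -0.579 for microglia, -0.645 for meningeal and -0.752 for leukocyte genes.

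**Figure D3:**
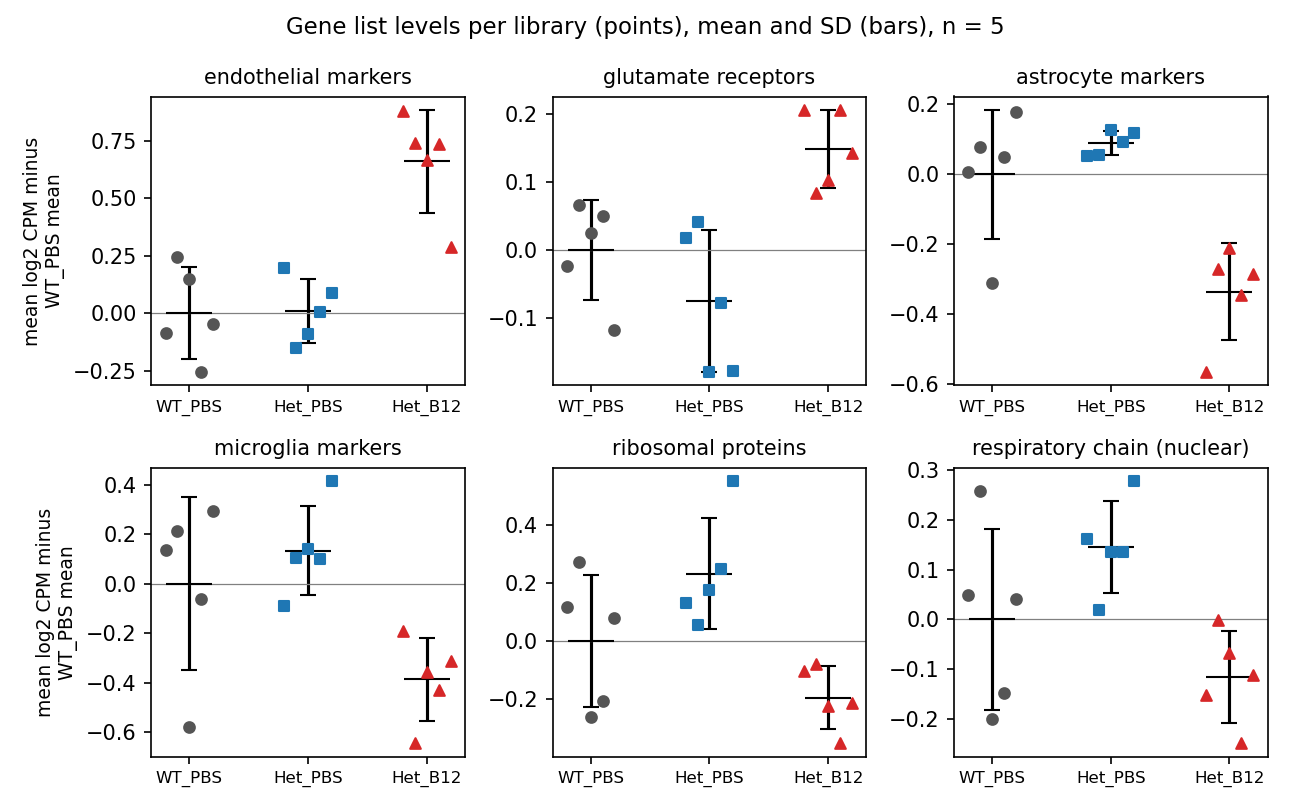
Mean log2 CPM of 6 gene lists relative to the WT_PBS mean (vertical axes) in the 3 groups (horizontal axes), with 1 point per library and bars for the mean and SD (n = 5). The endothelial level was 0.661 ± 0.224 in Het_B12, and WT_PBS 3 was the lowest WT_PBS library for astrocyte and microglia markers.

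Lists of ribosomal protein, respiratory chain and mitochondrially encoded genes lay lower with the vitamin. Of 76 cytosolic ribosomal protein genes, 42 fell, 0 rose and 34 did not pass; 55 fell adjusted over the list alone, for example Rps14 (-0.93 ± 0.11) and Rplp1 (-0.73 ± 0.10; camera adjusted p = 4.16e-34; adjusted p = 0.0821 with an estimated correlation). Of 72 nuclear respiratory chain genes, 18 fell, 1 rose and 53 did not pass, and adjusted over the list alone 29 fell and 1 rose. Ndufa2 and Uqcrh, subunits of complexes I and III, fell by 0.78 ± 0.11 each (camera adjusted p = 7.44e-14; adjusted p = 0.155 with an estimated correlation). Of 10 mitochondrially encoded genes 5 fell, and 6 adjusted over the list alone, with mt-Co1 at -0.71 ± 0.11 (camera adjusted p = 1.59e-06; adjusted p = 0.0979 with an estimated correlation). Changes followed transcript length: among the fifth of genes with the shortest transcripts (78 to 2092 nucleotides) 15 rose and 218 fell, and among the longest (5620 to 123179 nucleotides) 186 rose and 25 fell. Across genes, which are not independent replicates, Spearman's rho of length and log2 fold change was 0.257. Over the alternatives, the length offset among them, log2 fold changes ran from -0.788 to -0.337 for Rplp1 and from -0.867 to -0.42 for Ndufa2. For Rps14 they ran from -0.996 to -0.69, and no alternative ended the call of these 3 genes.

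A further 5 lists lay lower. Glutathione and antioxidant genes (34) had 8 lower and 26 not passing, and adjusted over the list alone 10 lower and 1 higher, led by the metallothionein genes Mt1 (-0.89 ± 0.13) and Mt2 (-1.04 ± 0.16; camera adjusted p = 8.77e-06; adjusted p = 0.0979 with an estimated correlation). Erythroid genes (10) had 5 lower, and 5 adjusted over the list alone, with Hbb-bt at -2.04 ± 0.31 (-1.40 without Het_PBS 3) and Hbb-bs at -1.71 ± 0.27 (-0.85 without Het_PBS 1 and Het_PBS 3; camera adjusted p = 1.56e-05; adjusted p = 0.155 with an estimated correlation); the share of haemoglobin counts was 0.0757% ± 0.0239 in Het_B12. Unfolded protein and heat shock genes (27) had 4 lower, and 6 adjusted over the list alone, with the chaperone gene Hsp90aa1 at -0.58 ± 0.11 (camera adjusted p = 0.00384; adjusted p = 0.253 with an estimated correlation). Fatty acid synthesis genes (32) had 3 lower, 1 higher and 28 not passing, and adjusted over the list alone 9 lower and 1 higher. Fabp5, a fatty acid carrier, fell by 0.91 ± 0.16 and the elongase gene Elovl6 rose by 0.60 ± 0.16 (adjusted p = 0.0818 without Het_PBS 1 and Het_PBS 3; camera adjusted p = 0.00517; adjusted p = 0.0822 with an estimated correlation). Fatty acid oxidation genes (27) had 2 lower and 1 higher, and adjusted over the list alone 6 lower and 1 higher, with the electron transfer gene Etfb at -0.63 ± 0.13 (-0.37, adjusted p = 0.105, with an offset for transcript length; camera adjusted p = 0.00781; adjusted p = 0.0821 with an estimated correlation).

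Among neuronal lists, 5 of 28 glutamate receptor genes rose and 23 did not pass, and 5 rose adjusted over the list alone. They included the kainate receptor gene Grik5 (0.94 ± 0.19) and the metabotropic receptor gene Grm4 (0.67 ± 0.15; camera adjusted p = 0.000913; adjusted p = 0.155 with an estimated correlation). With an offset for transcript length, the p of this list was 0.0847. Of 23 striatal projection neuron markers 2 rose, also adjusted over the list alone, with the dopamine receptor gene Drd2 at 1.00 ± 0.23 (camera adjusted p = 0.013; adjusted p = 0.346 with an estimated correlation). The striatal call was lost without Het_PBS 5 (0.101), without Het_PBS 1, and with Het_PBS 1 and Het_PBS 3 both left out (0.0529). Genes of GABA signalling (24) had 2 members higher, and adjusted over the list alone 3 higher and 5 lower (camera adjusted p = 0.803). Glutamate and glutamine metabolism (25) had 3 members lower, also adjusted over the list alone: Slc1a2 (-0.45 ± 0.10) and Slc1a3 (-0.46 ± 0.12), the glutamate transporters of astrocytes, and Glul (-0.50 ± 0.12; camera adjusted p = 0.215). The call of Glul was lost without Het_PBS 5 (adjusted p = 0.052) and with 1 surrogate variable (0.0607).

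Of the lists tied to the design, the Tbx1 neighbourhood had 3 of 28 genes higher, also adjusted over the list alone: Aifm3 (0.71 ± 0.22), Cldn5 and Pi4ka (0.39 ± 0.12), at a camera adjusted p of 0.108. With an offset for transcript length the list passed (0.0396, higher), while Pi4ka did not (0.129), and without Het_PBS 1 and Het_PBS 3 together Cldn5 did not pass (0.1). By DESeq2 Aifm3 did not pass (0.0703). The calls of Aifm3 and Pi4ka were lost in 7 and 8 of the 15 fits without 1 library (highest adjusted p 0.0986 and 0.101, both without Het_B12 1). Of 18 genes of vitamin B12 uptake and use, Prdx1, a peroxiredoxin gene that neighbours the cobalamin processing gene Mmachc, fell by 0.67 ± 0.14 (edgeR adjusted p = 0.00175), also adjusted over the list alone, and 17 did not pass (camera adjusted p = 0.752). The folate and methionine cycle had 1 of 25 genes lower, also adjusted over the list alone (camera adjusted p = 0.215).

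By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2540 genes had an unadjusted p under 0.05, and 917 (7.83%) had no overlap between the groups, against 0.794% by chance. Camera with its preset correlation called 15 of 48 lists, 3 higher and 12 lower; fry called 17, and with an estimated correlation 0 passed at a smallest adjusted p of 0.0821, while 14 had an unadjusted p under 0.05. The number of genes was 549 without Het_B12 1 and 509 without Het_PBS 1 and Het_PBS 3 together.

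Treated heterozygotes were then set against wild types given saline, which asks how far the treated brains stood from untreated normal ones. Between Het_B12 and WT_PBS 859 genes differed, 377 higher and 482 lower, and 118 by more than 2-fold. Flt1 rose 3.62-fold, from 19.8 ± 3.70 to 71.5 ± 15.8 CPM (SD, n = 5; log2 fold change 1.86 ± 0.20, edgeR adjusted p = 8.38e-08), S100b fell by 0.91 ± 0.10 on the log2 scale (3.30e-07) and C1qa by 0.96 ± 0.15 (9.02e-05). Ushbp1, the largest rise (3.38 ± 0.71, adjusted p = 0.00197; 4.06 without WT_PBS 2), had 86 reads in Het_B12 and 6 in WT_PBS, and Memo1 (2.57 ± 0.57) had 71 and 9. Dcp1a (2.23 ± 0.54), Muc3a (2.22 ± 0.67), the zinc transporter gene Slc39a2 (2.06 ± 0.65), the cytokine receptor gene Csf2ra (1.95 ± 0.33), the cell cycle kinase gene Cdc7 (1.93 ± 0.61), Tspan18 (1.91 ± 0.57) and Coro6 (1.88 ± 0.59) were also higher. Dcp1a overlaps a gene with reads on the opposite strand and is uncertain without a stated strand setting. Slc39a2 overlaps a gene with reads on its own strand and is uncertain under any strand setting. Muc3a was at 3.38 without WT_PBS 3.

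Mroh2a fell by 5.94 ± 0.45 on the log2 scale (edgeR adjusted p = 1.16e-11), from 50.0 ± 18.8 CPM, Slc2a9 by 4.92 ± 0.71 and Olfr432 by 4.47 ± 0.79. The predicted genes Gm15839, Gm26870 and Gm10800 fell by 3.93 ± 0.55, 3.76 ± 0.49 and 2.72 ± 0.53. Without Het_B12 1, Gm26870 was at -4.83 and Gm10800 at -3.33, and Gm15839 was at -4.79 without Het_B12 5, all on few reads. Pramel1 had 2 reads against 63 in WT_PBS, 39.3-fold fewer relative to depth (95% interval of counting error 10.4 to 332). S100a8 (-2.49 ± 0.61), Mpzl2 (-2.28 ± 0.51) and the chemokine gene Ccl6 (-2.24 ± 0.56) were lower. By limma-voom S100a8 (-1.91, adjusted p = 0.195) and Gm10800 (0.0549) did not pass. As in the comparison with Het_PBS, the receptor families were lower in these Het_B12 libraries, at no more than 25.9 CPM against at least 57.1 CPM in any PBS library.

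Endothelial, astrocyte and microglia markers differed here too, while the lists of oligodendrocytes (camera adjusted p = 0.529), their precursors (0.676), pericytes (0.676) and VEGF and Notch signalling (0.0698) did not pass. Of 21 endothelial markers 7 rose and 14 did not pass, and adjusted over the list alone 8 rose and 1 fell, with Slco1a4 at 1.22 ± 0.23 and Cldn5 at 1.44 ± 0.36 (camera adjusted p = 7.38e-08; adjusted p = 0.237 with an estimated correlation). Astrocyte markers (22) had 9 lower, and 11 adjusted over the list alone, with Gjb6 at -0.82 ± 0.15 (camera adjusted p = 4.53e-09; adjusted p = 0.267 with an estimated correlation). Microglia markers (21) had 7 lower, and 8 adjusted over the list alone, with Cx3cr1 at -0.64 ± 0.12 (camera adjusted p = 1.01e-05), and meningeal markers (17) had 6 lower by both counts, the second adjusted over the list alone, with the collagen gene Col1a1 at -1.33 ± 0.32 and Ptgds at -0.61 ± 0.14 (9.96e-05). Leukocyte markers (7) had 2 lower, and 3 adjusted over the list alone (0.0219). For these last 3 lists the adjusted p = 0.267 with an estimated correlation, and the leukocyte list was lost without WT_PBS 2 (0.0594). WT_PBS 3 stood lowest among the WT_PBS libraries for the astrocyte, microglia, meningeal and leukocyte lists.

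Ribosomal protein genes (76) had 22 lower, 2 higher and 52 not passing, and adjusted over the list alone 29 lower and 3 higher, with Rps14 at -0.80 ± 0.11 (camera adjusted p = 2.76e-10; adjusted p = 0.621 with an estimated correlation). Nuclear respiratory chain genes (72) had 15 lower and 1 higher, and adjusted over the list alone 21 lower and 4 higher, with Ndufa2 at -0.82 ± 0.11 and Atp5k at -0.82 ± 0.10 (camera adjusted p = 0.00012; adjusted p = 0.632 with an estimated correlation). That list no longer passed without WT_PBS 2 (0.0658) or with an offset for transcript length (0.719). Fatty acid synthesis genes (32) had 5 lower and 2 higher, and adjusted over the list alone 7 lower and 3 higher, with Fabp5 at -1.0 ± 0.16 (camera adjusted p = 0.015; 0.0594 without WT_PBS 2). Fatty acid oxidation genes (27) had 3 lower, and adjusted over the list alone 4 lower and 1 higher, with Etfb at -0.79 ± 0.13 (camera adjusted p = 0.043). For both lipid lists the adjusted p = 0.267 with an estimated correlation, and the oxidation list was lost without WT_PBS 2, WT_PBS 5 (0.12) or Het_B12 1, and with the length offset (0.0698). Striatal markers (23) had 4 higher, and 6 adjusted over the list alone, with Pde10a at 0.81 ± 0.16 and Drd2 at 0.83 ± 0.22 (camera adjusted p = 0.00233; adjusted p = 0.411 with an estimated correlation).

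In the Tbx1 neighbourhood 2 of 28 genes were higher, Cldn5 and Lztr1 (0.50 ± 0.15), and 3 adjusted over the list alone (camera adjusted p = 0.529). Prdx1 was the 1 gene of 18 in vitamin B12 uptake and use that passed, by both counts, the second adjusted over the list alone (-0.60 ± 0.14, edgeR adjusted p = 0.00567; camera adjusted p = 0.815). Ddx3y passed among 4 sex-linked genes (-0.41 ± 0.13, adjusted p = 0.0463), also adjusted over the list alone. GABA signalling genes (24) had 3 higher and 2 lower, and adjusted over the list alone 4 higher and 5 lower, with the vesicular transporter gene Slc32a1 at 0.67 ± 0.12 (camera adjusted p = 0.929). Glutamate and glutamine metabolism (25) had 1 higher, Slc38a1 (0.59 ± 0.13), and 2 lower, one of them Slc1a2 (-0.44 ± 0.10), by both counts, the second adjusted over the list alone (camera adjusted p = 0.984).

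By edgeR's test 2526 genes had an unadjusted p under 0.05 and 630 (5.38%) had no overlap between the groups, against 0.794% by chance. Camera called 10 of 48 lists, 2 higher and 8 lower, fry 10, and with an estimated correlation 0 passed at a smallest adjusted p of 0.237, while 8 had an unadjusted p under 0.05. The number of genes was 449 without WT_PBS 5, 477 without WT_PBS 1, 513 without Het_B12 2, 515 without Het_B12 1 and 1390 without WT_PBS 3 and Het_PBS 5 together, and 6 lists passed without WT_PBS 2. Calls of 9 of the 41 named genes were lost in at least 1 fit without a library. Slc39a2, Coro6 and Ddx3y were lost in 10 of the 15 fits, Cdc7 in 8 and Muc3a in 7. Tspan18 and Lztr1 were lost in 5, Drd2 in 4 and S100a8 in 1. The highest edgeR adjusted p came without WT_PBS 5 for Muc3a (0.125), Slc39a2 (0.143), Lztr1 (0.137), Ddx3y (0.16) and Drd2 (0.0775). It came without Het_B12 2 for Cdc7 (0.147) and Tspan18 (0.123), without Het_B12 1 for Coro6 (0.141) and without WT_PBS 1 for S100a8 (0.0512). By DESeq2 Slc39a2 (0.0622), Cdc7 (0.0631) and Coro6 (0.0519) did not pass, nor did Tspan18 with 1 surrogate variable (0.0596), Lztr1 in a fit of the 2 groups (0.0507) or Ddx3y without a filter on low counts (0.061).

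Whether the vitamin moved genes back towards wild-type levels was examined by correlating the genotype and vitamin fold changes across the 11718 genes, which are not independent replicates. Pearson's r was -0.368 and Spearman's rho -0.339. The 2 comparisons share the Het_PBS libraries with opposite signs, and counts simulated with no effect gave a mean r of -0.51. The covariance was -0.0459 against -0.0376 simulated, a difference of -0.00827. The simulation drew each gene independently, without variation shared across a library, and no spread of its covariances was kept. The size of this difference therefore cannot be judged. With the Het_PBS libraries divided into disjoint sets, the mean r was -0.0462 over 20 assignments (-0.0761 to -0.00184). In those 20 assignments the list medians of ribosomal protein genes were of opposite sign each time, at 0.0782 to 0.347 for genotype and -0.604 to -0.299 for the vitamin. Of the 48 lists 10 were of opposite sign in all 20, the mitochondrially encoded, respiratory chain, erythroid, astrocyte and glutathione lists among them. The assignments reuse the same Het_PBS libraries, no value without change was computed for this tally, and no genotype list passed with an estimated correlation (smallest adjusted p = 0.365). Other lists called for the vitamin were of opposite sign in 7 of 20 (endothelial markers), 6 (striatal), 13 (fatty acid synthesis), 16 (microglia), 17 (meningeal), 18 (glutamate receptors) and 19 (leukocyte). Differences between these tallies were not tested, and 30 of all 48 lists were of opposite sign more often than not.

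The vitamin and treated-against-wild-type comparisons share the Het_B12 libraries. Their fold changes correlated at r = 0.731 (rho 0.706) across genes, against 0.477 simulated with no effect. The covariance was 0.124 against 0.0344 simulated, a difference of 0.0897, with the same limits of the simulation. Disjoint Het_B12 sets gave a mean r of 0.435 (0.335 to 0.476). In both comparisons 180 genes were higher and 266 lower, 0 changed in opposite directions, and independent lists of these sizes would share 13.1 and 18.3. That number leaves out the shared libraries and the simulation, which gave 0, leaves out real effects, so neither is a value without change for these counts. Over all 3 groups, 908 genes differed by the edgeR F test, 556 without Het_B12 1.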

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

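Of the tests in this part, those of transcript length, of Gm42418 and mitochondrial genes, of equal library totals, of the wild-type slopes, of the 4 falling marker lists, of the 6 genes against receptor families and of ribosomal RNA reads were chosen after the result was seen. The tests of haemoglobin, of endothelial markers and of the receptor-family level were set before their own results, but they address patterns already seen.

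In groups of 5, a library was listed when its gap to the nearest other exceeded the 95% critical value of Dixon's test. Among 300 groups tested 20 were, and chance gives about 1 in 20, or 15. Het_B12 1 had 7 of them. It kept reads of genes nearly lost from the other Het_B12 libraries, at 4.09 CPM for Mroh2a (others 0 to 0.349), 5.00 for Gm26870 (0 to 1.40), 1.82 for Olfr432 and 0.909 for Pramel1 (others 0 for both). It also stood at 16.4 CPM for Pcdhgc5 (others 6.09 to 8.83), 313 for Uqcrh (377 to 399) and 0.217 for the log2 level of the Tbx1 neighbourhood (0.0393 to 0.0728). Het_PBS 5 had 4, at 44.2 CPM for S100a8 (others 7.02 to 12.1), 40.1 for Flt1 (18.6 to 23.9), 2590 for Glul (1600 to 1890) and 0.365 for the unfolded protein level (0.0962 to 0.167). In other Het_PBS libraries, Het_PBS 2 was at 12.3 CPM for Gm15839 (others 6.90 to 8.42) and 155 for Prdx1 (197 to 209), Het_PBS 3 at 46.6 for Miat (27.5 to 31.4) and Het_PBS 1 at 1850 for Rplp1 (2210 to 2340). Among Het_B12 libraries, Het_B12 3 was at 13.6 CPM for Sec14l5 (others 6.28 to 7.17) and 10.2 for Rgs11 (16.3 to 18.5), Het_B12 4 at 73.5 for Etfb (47.7 to 53.0) and Het_B12 5 at 5.93 for Pecam1 (10.7 to 12.2). Among WT_PBS libraries, WT_PBS 2 had 9.58% mitochondrial counts (6.32% to 7.06%).

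Group labels were redrawn to ask whether chance could give the counts of genes. For Het_PBS against WT_PBS the real count was 0 and the highest other was 18, so all 100 of 100 splits were as large by construction, which says nothing about chance. For Het_B12 against Het_PBS the real count was 851 and the highest other 8, and for Het_B12 against WT_PBS 859 and 428. Over the 3 groups they were 908 and 60. In each, 1 of 100 splits, the real one, was as large. That is the smallest share that 100 splits can give, so chance was made unlikely but was not excluded. The split with 428 genes exchanged WT_PBS 3 with Het_B12 5. Exchanging WT_PBS 3 with Het_B12 3, Het_B12 4, Het_B12 2 or Het_B12 1 gave 416, 378, 158 and 62 genes, which points to a structure of the samples.

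The shift between Het_B12 and Het_PBS was partly present in 1 wild-type library given saline. On 766 genes that differed between Het_B12 and WT_PBS, Het_PBS slopes ran from -0.0182 to 0.0202. These 766 genes were selected with WT_PBS 3 in the WT_PBS group and are another set than that used for WT_PBS 3. The Het_PBS slopes therefore cannot show whether a Het_PBS library varied as WT_PBS 3 did. On the 1100 genes that differed among the 10 heterozygous libraries alone, WT_PBS 3 deviated from the other WT_PBS libraries with a slope of 0.502. For WT_PBS 3, 84% of genes went in the same direction. On other features WT_PBS 3 stood with the PBS libraries. Its endothelial level was 0.150, against 0.286 to 0.880 in Het_B12. Its receptor-family level was 128 CPM, against at most 25.9 CPM in Het_B12. The other WT_PBS slopes ran from -0.237 to -0.0015, but each library was set against the rest of its group, so these slopes depend on WT_PBS 3. Over the 10 PBS libraries a score of the 1100 genes was computed, leaving out the marker lists. It ran against the mean of the astrocyte, microglia, leukocyte and meningeal lists. Pearson's r was -0.956 (permutation p = 0.00013, adjusted 0.00032 over 5 relations) and rho -0.915 (permutation p = 0.00069). Without WT_PBS 3 and WT_PBS 5, r was -0.826. An RNA composition that varies between libraries for other reasons than the vitamin would give such a relation. The score also subtracts the genes that fell in Het_B12, and unlisted genes of the same cell types can remain among them. Part of the relation may therefore be built in, and it does not show what caused the shift. The tables argue against a trend with transcript length, depth and the counts of Gm42418 and mitochondrial genes as the whole cause: 658 genes were called with a length offset and 710 with every library thinned to 1683258 counts, though the correlation of the score with depth was undecided (r = -0.306, permutation p = 0.41, adjusted 0.68; rho = -0.0182, p = 0.97; r = 0.225 without Het_PBS 5 and WT_PBS 3), and the changed share of Gm42418 and mitochondrial genes (18.3% to 13.8%) shifts all other genes by 0.0776 on the log2 scale, against a median absolute change of 0.605. Endothelial markers did not decide it (r = 0.126, permutation p = 0.75, adjusted 0.78; rho = -0.188, p = 0.61; r = -0.433 without WT_PBS 3 and WT_PBS 5). An effect of the vitamin stays open, and with no wild types given the vitamin and no batch in the labels it cannot be told apart from a preparation that differed for the Het_B12 libraries.

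Mroh2a, Slc2a9, Pramel1, Gm15839, Gm26870 and Gm10800 had 127 to 332 reads together in each PBS library and 2 to 42 in each Het_B12 library. The summed CPM of 1447 olfactory, vomeronasal and trace amine receptor genes, not counting Olfr432, was 5.2-fold lower in Het_B12 (exact two-sided permutation p = 0.00033), with 4.95% of those reads in the largest gene, and over the 10 PBS libraries it rose with the 6 genes (r = 0.92, permutation p = 0.00013, adjusted 0.00032; rho = 0.915, p = 0.00074; r = 0.905 without WT_PBS 4 and Het_PBS 3). Both values are consistent with a common background, for which genomic DNA carried into the PBS libraries is a candidate explanation. The tables argue against ribosomal RNA reads: the median log2 fall of the 6 genes was 4.51 times that of Gm42418, and they did not rise with it (r = 0.102, permutation p = 0.78, adjusted 0.78; rho = 0.115, p = 0.76; r = 0.0798 without Het_PBS 5 and WT_PBS 1). An effect of the vitamin on these genes was not tested apart from this and stays open, as does a different RNA isolation, since the labels name more than 1 procedure.

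Haemoglobin genes were highest in Het_PBS, with a mean log2 CPM of 10.8 against 9.7 in WT_PBS (exact permutation p = 0.063, adjusted 0.094 over 3 comparisons, n = 5) and 9.43 in Het_B12 (exact p = 0.024, adjusted 0.072). Het_B12 and WT_PBS differed by -0.27 (exact p = 0.44, adjusted 0.44). The SD of the log2 ratio of α to β chains over 15 libraries was 0.228 times the SD of their level, within the bound set in advance for blood left in the tissue, a candidate explanation, but 0.42 times without Het_PBS 1 and Het_PBS 3, and the ratio was higher in Het_B12 (0.733 to 0.983) than in WT_PBS (0.673 to 0.87) and Het_PBS (0.609 to 0.805), with overlap. A change of blood content with genotype or vitamin was not tested apart from these comparisons and stays open.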

How the results depend on the processing

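Of the alternatives, those without Gm42418 and mitochondrial genes, without pairs of libraries and with a length offset were chosen after seeing the data. The calls of Het_PBS against WT_PBS, 0 in all, were 40 without a low-count filter (30 higher, 10 lower), 5 with 1 surrogate variable, 1 without WT_PBS 3 and Het_PBS 5 together and 0 to 14 when each library was left out; the cause was not tested. Het_B12 against Het_PBS gave 549 to 1050 genes without 1 library and 509 without Het_PBS 1 and Het_PBS 3 together, where fewer libraries were compared. Het_B12 against WT_PBS gave 449 to 1268 genes without 1 library and 1390 without WT_PBS 3 and Het_PBS 5 together; the cause was not tested. For any difference among the 3 groups the count was 556 to 1283 without 1 library. With every library thinned to 1683258 counts, a test of depth chosen after seeing the data, the 3 comparisons gave 2, 710 and 653 genes. Under the other settings the counts of Het_B12 against Het_PBS, of Het_B12 against WT_PBS and over the 3 groups stayed within 1.5 times: 658 to 1100, 753 to 1118 and 730 to 1330, and genes shared with the reported calls of Het_B12 against Het_PBS and against WT_PBS had the same direction in each.

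Gene lists for genotype numbered 10, and 5 to 12 without 1 library, 4 without WT_PBS 3 and Het_PBS 5, 6 without Het_PBS 1 and Het_PBS 3, 0 with an estimated correlation and 0 by fry. For Het_B12 against Het_PBS they numbered 15, and 14 to 20 without 1 library; against WT_PBS 10, and 6 to 13. With an estimated correlation both were 0. The correlation of genotype and vitamin fold changes was -0.416 without a filter, -0.322 at a mean count of at least 50, -0.441 to -0.25 without 1 library and -0.0462 with disjoint Het_PBS sets, which removes the shared libraries. Of 3297 values of named genes under alternatives, 3124 kept their direction and side of the threshold, 141 no longer passed, 32 newly passed and 0 reversed. Size factors moved the median log2 fold change by under 0.01.

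The replicate numbers did not pair the libraries: 3 of 15 same-numbered pairs correlated above 0.1 (-0.205 to 0.246), and 4 of 15 libraries correlated best with their own number. With the replicate number as a block, 0, 830 and 800 genes and 10, 15 and 11 lists were called, 875 genes for any difference among the 3 groups, and the correlation was -0.371. Depth limits what could be seen in genes near 1.09 to 1.78 CPM, among them Tbx1.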

Other observations

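The genes and tallies of this part were chosen after their values were seen, and no explanation for them was tested. Meg3 rose from 3512 ± 544 to 9375 ± 1752 CPM between Het_PBS and Het_B12 (SD, n = 5; log2 fold change 1.42 ± 0.20 SE, edgeR adjusted p = 2.40e-05). Malat1, which is retained in the nucleus, rose from 4748 ± 393 to 9076 ± 1913 CPM (0.93 ± 0.16, 0.000289), Kcnq1ot1, which is also nuclear, from 206 ± 17.3 to 425 ± 40 CPM (1.05 ± 0.13, 3.87e-06) and Snhg11 from 776 ± 151 to 2260 ± 394 CPM (1.54 ± 0.23, 3.73e-05). For all 4 the groups did not overlap. WT_PBS 3 stood with the Het_B12 libraries, at 11650 CPM for Meg3 (other WT_PBS libraries 2921 to 5112), 10110 for Malat1 (3862 to 5055), 355.9 for Kcnq1ot1 (177 to 214) and 2844 for Snhg11 (603 to 967). Miat showed the same order, at 138 CPM in WT_PBS 3 and 15 to 43.9 CPM in the other WT_PBS libraries.

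Xist, which is transcribed from the inactive X chromosome of females, had 28 reads in Het_PBS 3, 2 in Het_B12 3 and 0 in the other libraries, beside reads of Y-linked genes in all 15. By fry, which compares a list with no other genes, the Tbx1 neighbourhood lay higher (adjusted p = 0.00379) and the folate and methionine cycle lower (0.00816) in Het_B12 than in Het_PBS, where camera gave 0.108 and 0.215.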
